A study of Drosophila melanogaster with 6 samples.

How the data were processed

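RNA was measured in eye discs, the larval tissue that forms the adult fly eye, taken from Drosophila melanogaster larvae late in the third instar. Per the labels, each of the 6 libraries came from 30 pairs of discs, was built with a stranded total RNA kit after ribosomal RNA depletion, and was read as pairs of 50 nt reads over 2 lanes of an Illumina HiSeq. The 3 groups hold 2 libraries each. All carry the sev-GAL4 driver, which is active in a subset of the developing retinal cells. The control carries a GFP transgene, the RNAi group adds a transgene against the long non-coding RNA Hsromega, and the overexpression group carries EP3037, an insertion through which the driver raises Hsromega. Nothing in the labels says whether the libraries of a group came from separate cultures, so the replicate spread that enters each p may be technical.

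The submitters' processing notes name TopHat, Bowtie, Cufflinks and Cuffdiff 2.1.1 and the dm6 genome build. The versions of TopHat, Bowtie and Cufflinks, the annotation and the mapping settings are not given in the sources used here. Each of the 2 deposited tables compares a treated group with the control at 15904 loci, and the authors pooled both libraries of a group into a single FPKM value, per the file headers. FPKM counts fragments scaled to transcript length and to the number of mapped fragments. No value per library was held in these tables, so the depth is unknown, no standard deviation or library-level test could be computed, and libraries could not be left out. The control FPKM values of both tables are identical. The test statistic, a score of the log2 ratio over its error, the p-value and the q-value (adjusted for multiple tests) are those of the authors' deposited Cuffdiff test. The last deposited column, which has another unit, marks p-values of 0.05 or less. A total of 637 loci join 2 or more genes under 1 value and are named with all their members. Whether fragments were assigned by strand is not given in the sources used here, so overlapping and antisense genes are uncertain, as are closely related copies such as the Jonah, Hsp70, histone and U2 snRNA genes and Sgs7 with Sgs8. The smallest deposited q-value, 0.00144, is the same in both tables and lies below what Benjamini-Hochberg gives over the tests of either table alone, so the set of tests behind the authors' q-values is unknown.

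The design fixed before the data were examined called a gene at the authors' q of 0.05 or less. A limma fit was planned only for files with values per library and was not run. The table for overexpression gives the treated group first, so its signs were turned to treated minus control. Fold values were computed from the deposited FPKM as log2 of treated over control, with no pseudocount for single genes; genes listed at 0 in a group have no fold. Gene lists and correlations used log2(FPKM + 0.1), which understates the change of low genes, over genes with FPKM of 1 or more in at least 1 group of that comparison. An error on the log2 scale was taken as the fold divided by the deposited statistic and is called the implied SE. It tends to exceed the error behind the deposited p. The normal score of that p was, at the median, 1.32 times the statistic for RNAi and 1.33 times for overexpression.

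A total of 33 gene lists were fixed beforehand, for eye development, signalling, stress, RNA processing and tissues that could be carried along with the discs; 11 of 401 listed symbols matched no locus and were left out. Each list median was placed among those of 10000 random lists of equal size drawn from 20 bins of mean expression. Random lists treat genes as independent, so a placement describes a list and is not a test across libraries. A second placement, chosen after the data were examined, drew from 5 bins of expression by 10 of transcript length. The text names Hsromega, w and sev, and takes its other genes from a set fixed by rule: the 12 raised and 12 lowered called genes with the largest fold among those with FPKM of 5 or more in the higher group and above 0 in both, leaving out small RNA genes (all named); up to 4 members of each list with the smallest q (some named as examples); and up to 6 genes per direction called in both comparisons. Other genes are named as chosen after their values were seen.

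Transcript lengths were taken from the Ensembl 115 annotation of the dm6 assembly, in which 97.7% of the loci had a match, and coordinates are 1-based. The trend of the fold with the longest transcript was measured as a running median of the 250 genes on each side. For a corrected fold, each deposited p was rescaled to the new fold and called at the largest p that the authors called, 0.00395; genes listed at 0 in a group or without a length kept their deposited p and were counted apart. The list placement and the length correction were tested on simulated data. Lists of 15 unchanged genes fell outside the central 95% in 5% of draws for RNAi (9823 genes) and 4% for overexpression (9907 genes), and lists shifted by 0.5 were found in 91% of draws in each. A true change of 1 in 200 genes was recovered as 0.98 for RNAi and 0.95 for overexpression. These simulations gave each gene independent noise and drew lists and changed genes at random. They did not test lists whose genes vary together, or real changes concentrated in long genes.

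For the overlap and the correlation of the comparisons, 100 sets of unchanged groups were simulated against a shared control. The variance of a group mean was set to 0.5 times the variance of the direct difference between the treated groups, per bin of expression, which assumes that the control varies alike and includes any real difference between the treated groups. With equal variance in all groups, a Pearson r near 0.5 is fixed in advance. This noise model was chosen after the output of a first version, which took its noise from the implied SE, had been seen: a few extreme errors had given that version a covariance far above the observed one. Alternatives were another q, a fold minimum, filters on FPKM, q recomputed over the genes of each table, genes listed at 0 left out, recentring on the median gene, small RNA genes left out and another pseudocount; the length correction and 3 other settings, and the shared calls with q recomputed, were added afterwards. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. For the run of loci near 0 on chromosome 3R described among the other observations, low loci were those with a control FPKM of 0.3 to 2.5, near 0 meant under 10% of the control, and loci with the same span were counted once; these limits were set after the run had been seen, and the count by span after a first version of the test.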

Results

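Ribosome-depleted total RNA was sequenced from the eye discs of larvae late in the third instar in 3 groups of 2 libraries: a control, a group labelled RNAi and a group labelled overexpression. Both treatments target Hsromega, a heat-inducible long non-coding RNA whose nuclear transcripts organise the omega speckles that hold hnRNP proteins. The comparisons ask which genes differ from the control when Hsromega is lowered or raised through the sev-GAL4 driver. Values are the authors' FPKM, pooled per group, so they carry no replicate spread and the depth behind them is unknown. Of 15904 loci, 9529 reached FPKM of 1 in the control, 9245 in the RNAi-labelled group and 9414 in the overexpression-labelled group.

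The targeted gene was not called in either comparison. Hsromega (chromosome 3R, 21296127 to 21317836, plus strand, annotated as a non-coding RNA with a longest transcript of 21216 nt) stood at FPKM 202 in the control, 204 in the RNAi-labelled group and 376 in the overexpression-labelled group. The authors' deposited table gives q = 0.997 for RNAi at a log2 fold of 0.014 and q = 0.758 for overexpression at 0.90, a 1.86-fold higher level. The implied SE from the authors' deposited table was 2.20 and 2.26, by which neither a fall nor a rise of a few fold was detectable at the level of whole discs. The deposited p for Hsromega correspond to smaller errors, so the smallest detectable change is uncertain. After the trend with length was subtracted, its log2 fold was 1.08 for RNAi, higher rather than lower than the control, and 2.13 for overexpression. The target gene therefore does not check the labels, and directions below are those of the groups as labelled. The locus that joins w with CG32795, where w is the eye pigment transporter gene used as a transgene marker, was at 61.7 in the control, 77.8 in the RNAi-labelled group and 86.1 in the overexpression-labelled group. The sevenless receptor gene sev was at 14.7, 6.23 and 5.32 in control, RNAi-labelled and overexpression-labelled discs, with q = 0.320 for RNAi in the authors' deposited table.

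**Figure D1:**
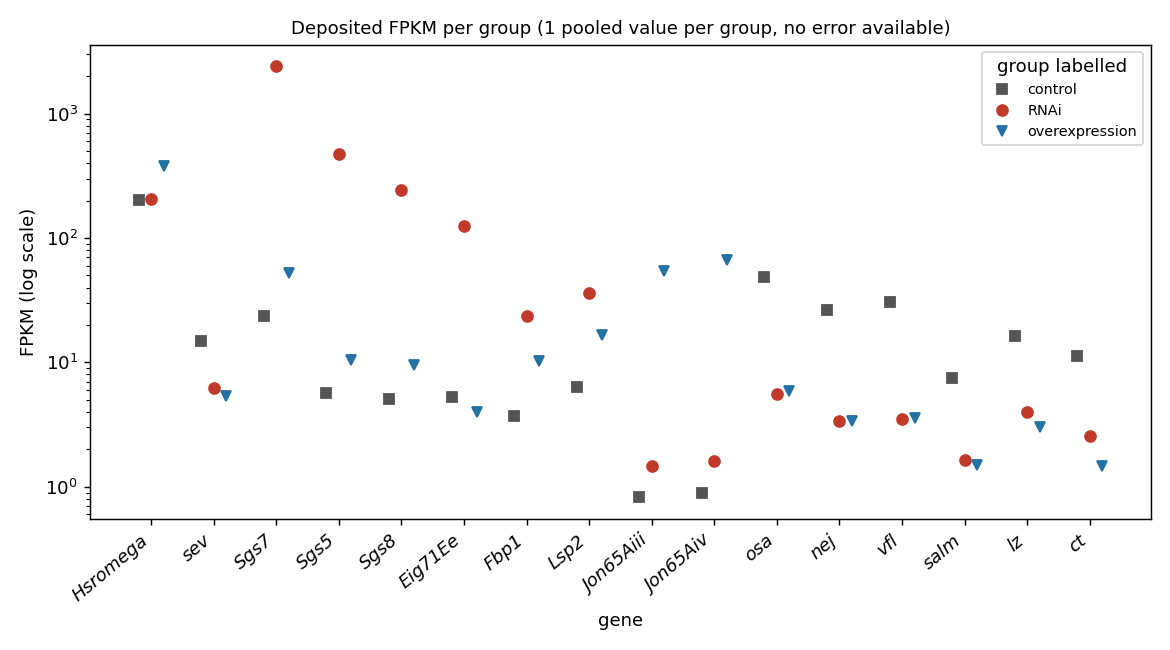
Deposited FPKM of 16 genes on a log axis, 1 pooled value per group (squares control, circles RNAi, triangles overexpression), with no error available. Hsromega lies at 202, 204 and 376, Sgs7 at 23.8, 2405 and 52.6, and Jon65Aiv at 0.886, 1.63 and 66.7.

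In the RNAi-labelled discs, salivary glue and fat body genes rose and a set of mostly long genes fell. Sgs7, which encodes a salivary glue protein (chromosome 3L), went from FPKM 23.8 to 2405, a 101-fold rise with an implied SE of 1.01 on the log2 scale from the authors' deposited table. Sgs7 and Sgs8 are related neighbours, so how fragments were divided between them is uncertain. Other raised genes among the largest changes included the glue genes Sgs8 (5.05 to 244) and Sgs5 (5.63 to 476), CG7587 next to Sgs5 (1.24 to 156), the ecdysone-induced gene Eig71Ee (5.25 to 124), the peptidoglycan recognition gene PGRP-SB2 (1.07 to 40.6), CG34296 (3.19 to 118) and the odorant-binding protein gene Obp99b (11.1 to 75.6). CG34166 went from 4.09 to 49.5, alphagamma-element:CR32865 from 4.80 to 39.1 and CG13840 from 0.458 to 7.10. The authors' deposited table called 93 of 11314 tested genes, 24 raised and 69 lowered, at log2 folds of at least 1.48 in size among those with values in both groups. Of these, 14 were listed at 0 in 1 group, with 6 raised and 8 lowered. With Benjamini-Hochberg recomputed over the 11314 tested genes of the authors' deposited table, 14 genes passed. All 14 stood at 5e-05, the smallest p that Cuffdiff gave in either comparison. These, named after their values were seen, were Sgs5, Sgs7, Sgs8, Eig71Ee, Fbp1, CG34296, Obp99b and alphagamma-element:CR32865 raised, and Dscam1, CG4408, CG11122, CG3916, CR43477 and the locus of nwk and mir-4940 lowered. Of the 69 lowered genes, 6 lie within 18.1 kb of chromosome 3R and include CG3916 and CR43477, both listed at 0 in the RNAi-labelled group. With p taken from the test statistic and folds recentred, 13 genes were raised and 1 lowered, of which 7 raised and 0 lowered were among the 93 calls. At p of 0.05 or less, unadjusted, 509 genes stood in the authors' deposited table, against 566 that 5% of the tests would give.

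Of the salivary gland list, 4 of 7 tested members rose in the RNAi-labelled group over all genes, and 4 when adjusted over the list alone. The median of its 6 expressed members was 5.05, above all 10000 random lists matched on expression and all matched on length as well. Sgs3, also a glue gene, was not called at 7.74 in the control and 15.6 in the RNAi-labelled group. Sgs4, named after its values were seen, was not called at 4.15 and 30.1. Of the fat body list, 4 of 7 tested members rose over all genes and 6 when adjusted over the list alone, with a median of 2.30 at the 100th percentile on both placements. The fat body protein genes Fbp1 went from 3.71 to 23.4 and the locus with Fbp2 from 4.18 to 35.3, and the larval serum protein genes Lsp2 from 6.29 to 36.2 and Lsp1gamma from 7.15 to 24.6. In the overexpression-labelled group no salivary gland member was called and the list median was 0.24 at percentile 88.2, or -0.15 after the length trend was subtracted, 0.49 at percentile 97.8 with no filter and 0.89 at percentile 99.9 at FPKM of 5 or more; the RNAi-labelled over overexpression-labelled difference had a median of 4.80, at the 100th percentile of random lists.

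Among the largest falls in the RNAi-labelled discs were those of osa, a subunit of the Brahma remodelling complex, from 48.7 to 5.54, nej, the CBP histone acetyltransferase, from 26.3 to 3.37, vfl, the zelda transcription factor, from 30.8 to 3.52, and disco, a zinc finger gene, from 11.3 to 1.60. The carboxypeptidase-like gene CG4408 fell from 29.8 to 3.34 and CG11122 from 12.7 to 1.24. CG13705 fell most among these, from 10.4 to 0.464, and CG44774 fell to 3.39 at a log2 fold of -3.37, Mipp1, a phosphatase gene, fell from 5.75 to 0.662, sbb from 46.0 to 6.09, CG11873 from 28.0 to 3.92 and CG32249 from 10.3 to 1.47. The implied SE from the authors' deposited table was 0.96 for osa, at a log2 fold of -3.14. Fold changes followed transcript length: lowered genes had a median longest transcript of 5101 nt and raised genes 743 nt, against 1841 nt over all expressed genes. After the trend with length was subtracted, a setting chosen after the data were examined, 15 of 60 lowered and 17 of 17 raised genes with a fold and a length still passed, and the calls among such genes were 20 raised and 22 lowered. Genes without a fold or a length kept their p under this setting and are left out of these counts.

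Eye development genes were lower in the RNAi-labelled discs, mostly without passing as single genes. In the list of photoreceptor and cone cell fate genes, 1 of 21 tested members fell, salm, a zinc finger gene of R7 and R8 (7.48 to 1.65), none when adjusted over the list alone, and the median was -1.37, below all random lists matched on expression and below all matched on length as well. The homeobox gene ct was at 11.4 and 2.57 and the Runt-type gene lz at 16.4 and 3.99; neither was called. The retinal determination list had no call among 14 tested members and a median of -0.86, at percentile 0.02 of random lists and 0.42 of those matched on length, with ptc, the Hedgehog receptor, at 29.7 and 8.84. Ecdysone response genes had a median of -0.95 and no call among 18, at percentile 1.47 when matched on length. After the length trend was subtracted, the medians of these lists were -1.002 for photoreceptor and cone cell fate, -0.46 for retinal determination and -0.30 for the ecdysone response. The EGFR, Sevenless and Ras pathway had a median of -0.55 with no call among 28, at percentile 0.01 and 5.62.

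The omega speckle and hnRNP proteins, which bind Hsromega transcripts, had no call among 13 tested in the RNAi-labelled group, with a median of -0.76 at percentile 0.18 of lists matched on length, or -0.27 after the length trend was subtracted. Of its members, nonA was at 21.1 and 4.97 and Hrb87F at 77.3 and 33.5. Heat shock genes had a median of 0.90, at the 100th percentile on both placements, with no call among 14: Hsp67Bc was at 27.1 and 86.7, and Hsp68 at 16.8 and 56.7. Cuticle protein genes had a median of -0.84, below all random lists on both placements, and Lcp65Ac fell to 4.34 at a log2 fold of -2.53 as the 1 call of 73, with none when adjusted over the list alone. Muscle markers had a median of -0.53 at percentile 0.075 when matched on length, with no call among 15. The brain neuron list had 1 fall, of brp, a synaptic active zone gene, from 3.99 to 0.599, also when adjusted over the list alone, and a median of -0.28, which turned to 0.12 after the length trend was subtracted.

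Other lists had no call in the RNAi-labelled group unless stated, over all genes or adjusted over the list alone. Of 32 lists with enough expressed members, 18 medians lay outside the central 95% of random lists and 12 outside that of lists matched on length. If the genes of a list varied independently, 1.6 would lie outside. Genes of a list can vary together, so this is not the number that unchanged groups would give. Medians were 0.04 for SR proteins, -0.17 for constitutive chaperones, -0.10 for the Jun kinase pathway, -0.71 for the JAK/STAT pathway, 0.15 for apoptosis and -0.41 for the Notch pathway, where that of the Jun kinase pathway turned to 0.13 after length. They were 0.19 for eye pigment genes, -0.57 for phototransduction, 0.32 for antimicrobial peptides, 0.16 for small RNA silencing, -0.12 for the cell cycle and 0.11 for detoxification, where that of eye pigment genes turned to -0.13 at FPKM of 5 or more. Cytoplasmic ribosomal proteins stood at 0.36, mitochondrial ribosomal proteins at 0.23, histones at 0.85 over 3 expressed loci (-0.25 with no filter), and small non-coding RNA genes at 0.55 with 1 lowered of 354, also when adjusted over the list alone; that locus joins mir-4940 with the protein-coding gene nwk, so the call does not single out a small RNA. Haemocyte markers stood at 0.11, gut markers at 0.78 over 5 expressed members (0.056 with no filter), glia markers at 0.04, germline and testis markers at -0.08 and X dosage compensation genes at -0.33. After the length trend was subtracted, 7 list medians came to lie inside the central 95% of random lists. These were the EGFR pathway at -0.11, the Notch pathway at -0.07, antimicrobial peptides at 0.06, detoxification at 0.016, mitochondrial ribosomal proteins at 0.023, histones at 0.59 and small non-coding RNA genes at 0.07; small RNA silencing at 0.41 and haemocyte markers at 0.56 came to lie outside it. Those of cytoplasmic ribosomal proteins, the JAK/STAT pathway, phototransduction and X dosage compensation became 0.14, -0.34, -0.34 and -0.04. For small non-coding RNA genes the subtraction cannot decide, since these loci make up much of the trend at their own length (0.51). Among lists matched on length their median lay at the 100th percentile. With no filter on FPKM, antimicrobial peptides stood at 0.09, inside the central 95%, as did detoxification at 0.15 at FPKM of 5 or more; phototransduction at -0.54 with pseudocount 1 and cytoplasmic ribosomal proteins at 0.37 without small RNA genes lay outside it. No locus of the mitochondrial genome list was found in the tables.

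**Figure D2:**
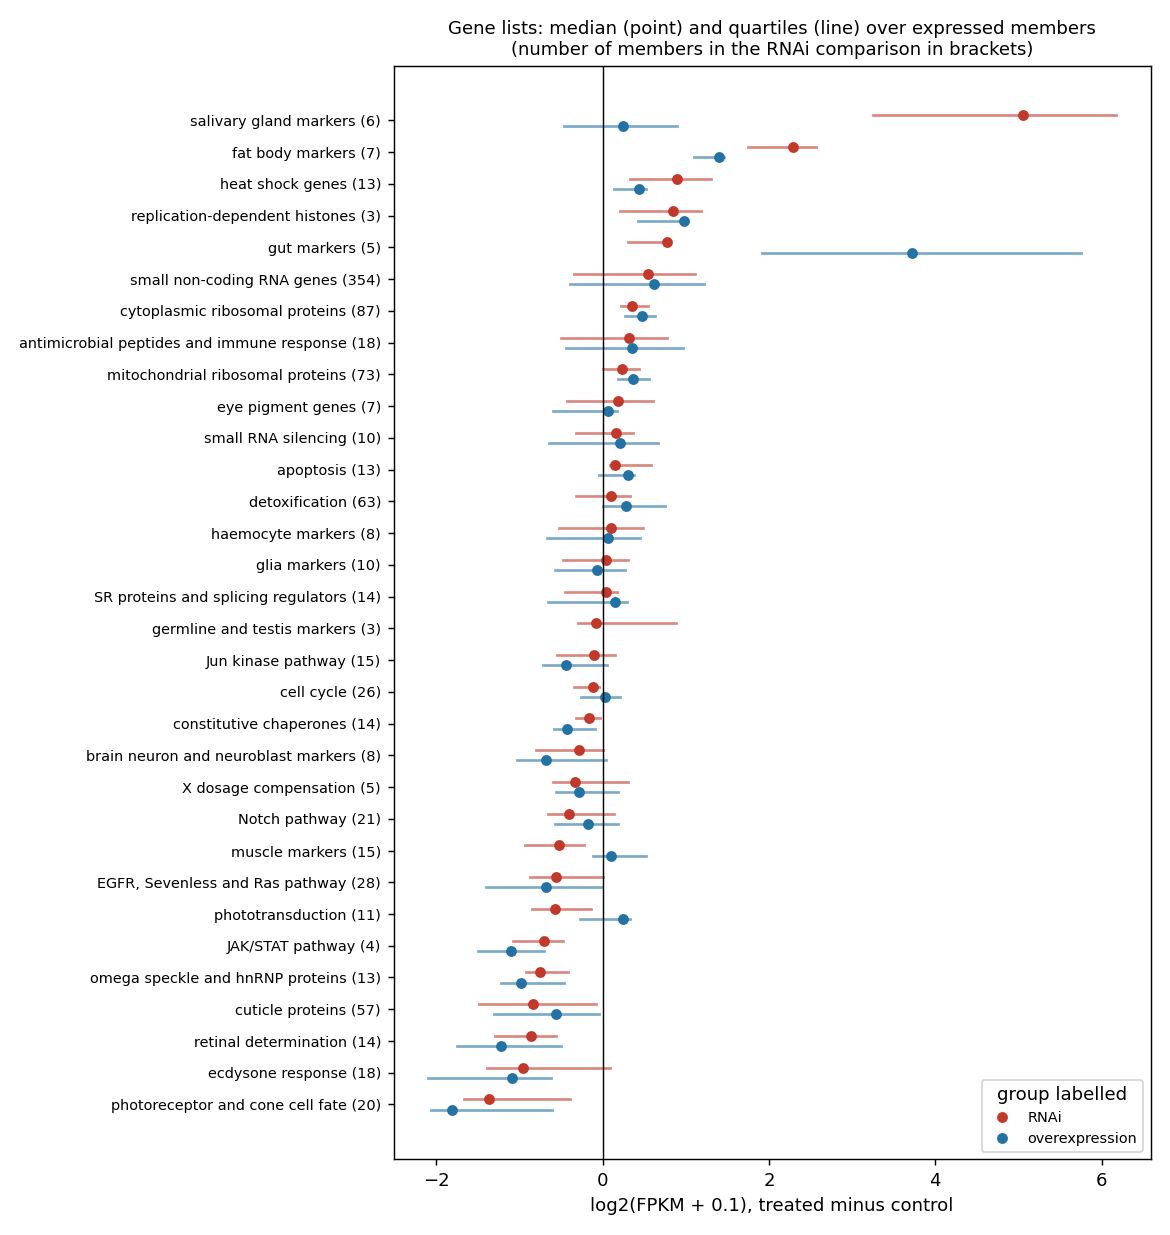
Median (points) and quartiles (lines) of the log2(FPKM + 0.1) difference from the control over the expressed members of each gene list, for the groups labelled RNAi and overexpression. Salivary gland markers lie at 5.05 and 0.24 (the latter -0.15 after the length trend was subtracted, 0.49 with no filter and 0.89 at FPKM of 5 or more), gut markers at 0.78 and 3.72 (0.056 and 0.89 with no filter on FPKM), and photoreceptor and cone cell fate genes at -1.37 and -1.81.

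In the overexpression-labelled discs, few genes rose, and genes of photoreceptor fate and retinal determination were among the many that fell. Genes that rose included the Jonah serine protease genes Jon65Aiv (chromosome 3L, 0.886 to 66.7) and Jon65Aiii (0.824 to 54.0) and the related yip7 (0.747 to 29.7). Jonah genes encode digestive enzymes of the gut, and the division of fragments between the close copies Jon65Aiii and Jon65Aiv is uncertain. The implied SE from the authors' deposited table was 1.23 for Jon65Aiv, at a log2 fold of 6.24. CG6933 went from 0.212 to 7.07, pst from 2.36 to 14.7, CG30345 from 3.04 to 10.1, CG34166 from 4.09 to 25.3, and the snRNA:U2:34ABa locus from 10.7 to 708. The division of fragments between copies of U2 snRNA is uncertain too, so this value does not show that U2 snRNA rose as a whole. The authors' deposited table called 136 of 11372 tested genes, 15 raised and 121 lowered, of which 8 were listed at 0 in 1 group. With Benjamini-Hochberg recomputed over the genes of the authors' deposited table, 0 genes passed, the smallest adjusted value being 0.0948, and 701 genes had an unadjusted p of 0.05 or less against 569 that 5% of the tests would give. Cuffdiff gave no p below 5e-05 in either comparison, and 6 genes stood at it here against 14 for RNAi. The counts of 0 and 14 hang on this limit and do not measure a difference in evidence. With p from the test statistic 11 genes passed here and 16 for RNAi. Lowered genes had a median longest transcript of 5981 nt, and after the length trend was subtracted 18 of 117 lowered and 5 of 10 raised genes with a fold and a length still passed, with 10 raised and 20 lowered calls among such genes. With p taken from the test statistic and folds recentred, 9 genes were raised and 2 lowered, of which 4 raised and 0 lowered were among the 136 calls.

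Photoreceptor and cone cell fate genes had 5 falls among 21 tested in the overexpression-labelled discs, 7 when adjusted over the list alone, with a median of -1.81 below all random lists on both placements. The genes that fell included ct (11.4 to 1.46), lz (16.4 to 3.03), ss, a bHLH-PAS gene of R7 subtype choice (9.27 to 2.00), and salm (7.48 to 1.49). The retinal determination list had 2 falls among 14, toe (4.07 to 0.605) and ptc (29.7 to 7.80), 3 when adjusted over the list alone, and a median of -1.22 at percentile 0.09 when matched on length. Ecdysone response genes had 1 fall among 18, Blimp-1 (35.1 to 5.53), 3 when adjusted over the list alone, and a median of -1.09 at percentile 1.72 when matched on length. After the length trend was subtracted, the medians of these lists were -1.26, -0.67 and -0.63. The EGFR, Sevenless and Ras pathway had 1 fall among 28, of the ETS repressor gene aop (67.7 to 12.9), none when adjusted over the list alone, and a median of -0.68 at percentile 8.84 when matched on length. The gene dome, the receptor of the JAK/STAT pathway, fell from 25.3 to 5.49 as 1 of 7 tested, and H, the Notch pathway repressor, from 18.1 to 3.55 as 1 of 21, both also when adjusted over their lists alone. SRm160, a splicing coactivator, fell from 17.7 to 4.49 as 1 of 14 splicing regulators, also when adjusted over the list alone, and their median was 0.15.

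Other large falls in the overexpression-labelled discs were CG9021 (12.3 to 0.446), disco (11.3 to 1.10), osa (48.7 to 5.89), Np, a transmembrane protease gene (11.6 to 1.36), and Incenp, a chromosomal passenger gene (32.8 to 3.90). CR40962, which had no match in the annotation, fell from 15898 to 1278, the non-coding gene CR43283 from 6.39 to 0.460, CG10555 from 25.7 to 2.54, HERC2, a ubiquitin ligase gene, to 1.24 at a log2 fold of -3.14, vfl from 30.8 to 3.61, CG15021 from 6.78 to 0.803 and CG11122 from 12.7 to 1.18. The implied SE from the authors' deposited table was 0.92 for osa, at a log2 fold of -3.05. The locus that joins RpL23A with Uhg7 fell from 552 to 105 as 1 of 89 cytoplasmic ribosomal protein loci, none when adjusted over the list alone, with a list median of 0.48, and brp fell from 3.99 to 0.446, also when adjusted over the list alone, with a median of -0.68 for the brain neuron list, which turned to 0.30 after length.

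Gut markers had 2 of 13 tested members raised, both also when adjusted over the list alone, with a median of 3.72 over 10 expressed members at the 100th percentile on both placements. Only 1 of the 10 reached FPKM of 1 in the control, so most entered the list through their level in the overexpression-labelled group. With no filter on FPKM the median was 0.89, still at the 100th percentile, and that of the RNAi-labelled group, 0.78 over another set of 5 members, was 0.056. The RNAi-labelled over overexpression-labelled difference had a median of -3.79 over 11 members under the same kind of filter, below all random lists. Fat body markers had a median of 1.40 at the 100th percentile on both placements, with no call over all genes and 3 raised when adjusted over the list alone. The omega speckle list had a median of -0.99 at percentile 0.14 when matched on length, or -0.51 after the length trend was subtracted, with no call among 13 and Hrb87F at 77.3 and 23.5. Small non-coding RNA genes had 3 raised of 353 tested, 1 when adjusted over the list alone, and a median of 0.62. The 3 were snRNA:U2:34ABa, snoRNA:Psi28S-3342 and a locus that joins mir-184 with CG17048 and CR44206. Of 31 lists, 16 medians lay outside the central 95% of random lists and 13 outside that of lists matched on length. With independently varying genes 1.55 would lie outside, under the same limit as for RNAi. Lists without a call, over all genes or adjusted over the list alone, had medians of 0.44 for heat shock, -0.43 for constitutive chaperones, -0.44 for the Jun kinase pathway, 0.30 for apoptosis, 0.07 for eye pigment (-0.07 after length and -0.0022 at FPKM of 5 or more), 0.25 for phototransduction and 0.35 for antimicrobial peptides. They were 0.21 for small RNA silencing, 0.03 for the cell cycle (-0.0071 when recentred), 0.28 for detoxification, -0.56 for cuticle proteins, 0.37 for mitochondrial ribosomal proteins (-0.015 after length) and 0.98 for histones. Muscle markers stood at 0.10. Haemocyte markers stood at 0.07, or -0.63 at FPKM of 5 or more. Glia markers stood at -0.07 and X dosage compensation genes at -0.28, which turned to 0.09 and 0.10 after length, while the JAK/STAT list stood at -1.10 over 4 expressed members and the Notch list at -0.18. With no filter on FPKM the JAK/STAT list stood at -0.50 and antimicrobial peptides at 0.25, both inside the central 95%, as were antimicrobial peptides at 0.39 at FPKM of 5 or more. Without small RNA genes the Notch list at -0.22 and cytoplasmic ribosomal proteins at 0.48 lay outside it. After the length trend was subtracted, the EGFR pathway at -0.18 (percentile 3), the Jun kinase pathway at -0.20, antimicrobial peptides at 0.11, histones at 0.46, small non-coding RNA genes at 0.05 and mitochondrial ribosomal proteins came to lie inside the central 95% of random lists. The Notch pathway at -0.25, small RNA silencing at 0.68 and haemocyte markers at 0.44 came to lie outside it. Those of the JAK/STAT pathway, heat shock, cuticle proteins, cytoplasmic ribosomal proteins, splicing regulators, apoptosis, detoxification and muscle became -0.62, 0.26, -0.95, 0.10, 0.05, 0.16, 0.18 and 0.19. Small non-coding RNA genes again made up much of the trend that was subtracted from them. Among lists matched on length their median lay at percentile 98.6. The germline and testis list had no call among 4 tested and too few expressed members for a median.

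At the q of the authors' deposited table, 44 genes were called in both comparisons, 43 lowered and 1 raised, and none in opposite directions. With Benjamini-Hochberg recomputed within each table from Cuffdiff's p, 0 genes were shared, since overexpression then had no call; 509 and 701 genes had an unadjusted p of 0.05 or less in the authors' deposited tables. The raised gene was CG34166, at 4.09 in the control, 49.5 in the RNAi-labelled group and 25.3 in the overexpression-labelled group, and osa, nej, vfl, sbb, CG44774 and CG11122 had the largest smaller fold among the lowered. At q of 0.01 or less 5 were shared, and 3 with p taken from the test statistic. Independent lists of these sizes would share 0.752 lowered and 0.0162 raised genes among 11099 tested in both, and unchanged groups against a shared control shared 10.7 on average and 19 at most in 100 simulations. Across 9716 genes, which are not independent replicates, the fold changes had a Pearson r of 0.73 and a Spearman rho of 0.80, where simulated unchanged groups against a shared control gave a mean Pearson r of 0.50. That 0.50 was fixed by giving all groups equal variance, so it is not a level estimated from the data. The covariance of the fold changes was 0.855 over the 9714 genes tested in both, against 0.315 for simulated unchanged groups, a difference of 0.540. The 0.315 rests on the same assumption. With 2 control libraries pooled into 1 value the control could not be split, so the part owed to the shared control was not measured.

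The 2 groups also shared a trend with transcript length. Among expressed genes the median difference from the control went from 0.58 at 200 nt or less to -1.14 above 12000 nt in the RNAi-labelled group, and from 0.68 to -1.33 in the overexpression-labelled group. Spearman's rho across genes was -0.416 over 9823 genes and -0.502 over 9907. Of the lowered genes with a length, 41 of 68 in the RNAi-labelled group and 93 of 120 in the overexpression-labelled group had a transcript over 4000 nt. After the trend was subtracted, 7 genes were called in both comparisons. Simulated unchanged groups with 44 RNAi calls and 31 overexpression calls shared 2.55 on average and 7 at most. Those counts lie below the 58 and 39 calls after length over all genes, so the 7 and the 2.55 may not cover the same genes. Small non-coding RNA genes had a median longest transcript of 137 nt. They held 39.4% of the FPKM sum in the control, 47.5% in the RNAi-labelled group and 47.0% in the overexpression-labelled group. FPKM divides by length, so this is not a share of fragments. These loci make up much of the short end of the trend, so the share and the trend cannot be told apart. The FPKM sums were 881816, 1205883 and 1245859.

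**Figure D3:**
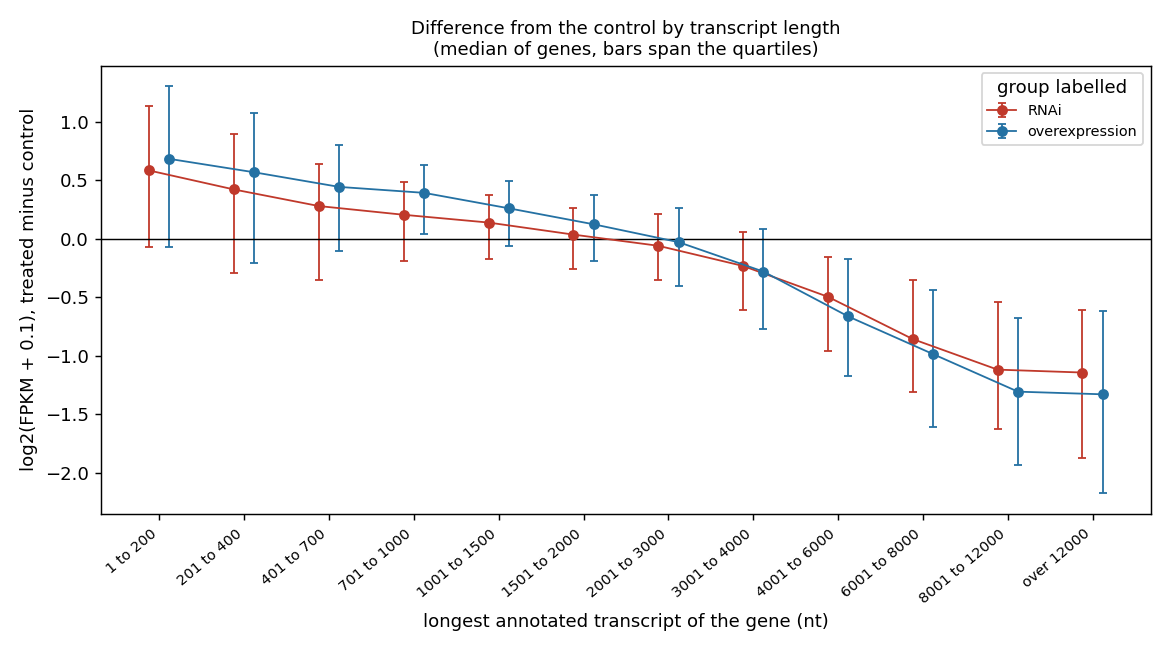
Median difference from the control on the log2(FPKM + 0.1) scale (points) and quartiles (bars) of expressed genes in 12 bins of longest annotated transcript, for the groups labelled RNAi and overexpression. Both lines go from above 0 at short transcripts (0.58 and 0.68) to below 0 at long ones (-1.14 and -1.33).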

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

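The length correction, the rescaled p, the shared calls with Benjamini-Hochberg recomputed, the p from the statistic without recentring and the unadjusted p were chosen after the data were examined. No paired analysis was possible because the deposited columns carry no value per library, although the labels share replicate numbers; fits with the replicate as a term and fits without each library were not run for the same reason, and depth limits could not be set. The 93 RNAi calls became 34 at q of 0.01, 14 with Benjamini-Hochberg recomputed over all tested genes or over those with FPKM of 1 or more, 13 without small RNA genes, 14 when recentred with p from the statistic and 16 without the recentring, 58 after the length trend was subtracted and 509 at an unadjusted p of 0.05. The 136 overexpression calls became 31 at q of 0.01, 0 with Benjamini-Hochberg recomputed in each of these 3 ways (Cuffdiff's p, with 701 at an unadjusted p of 0.05), 11 with p from the statistic with or without recentring and 39 after the length trend was subtracted. Recentring with p from the statistic moved the RNAi split from 24 raised and 69 lowered to 13 raised and 1 lowered, and that for overexpression from 15 and 121 to 9 and 2. Of the main calls, it kept 7 raised and 0 lowered for RNAi, and 4 and 0 for overexpression. The p from the statistic alone gave 13 and 3, and 9 and 2, so the centring was not the main reason. Benjamini-Hochberg recomputed on the deposited p gave 8 raised and 6 lowered for RNAi and no call for overexpression. The adjustment alone thus changed the split, and the p from the statistic changed it again. The recomputed counts of 14, 13 and 0 hang on the smallest p that Cuffdiff gave, 5e-05, at which 14 RNAi and 6 overexpression genes stood. The set of tests behind the deposited q is unknown, and for the other settings the cause was not tested. The 2-fold minimum kept all 93 and 136, recentring with the deposited p rescaled gave 87 and 144, and leaving out genes listed at 0 left 79 and 128. The 44 shared calls became 5 at q of 0.01, 3 when recentred with p from the statistic 7 after length and 0 with Benjamini-Hochberg recomputed in each of the 3 ways (Cuffdiff's p), and were 42 or more under FPKM filters or without small RNA genes at the deposited q. The correlation of 0.73, beside the 0.50 that the simulation fixed in advance, was 0.59 with no filter, 0.74 at FPKM of 5 or more, 0.74 with pseudocount 1, 0.79 without small RNA genes and 0.71 after length. The fold of Hsromega stayed uncalled under every setting tried, from 0.014 to 1.08 for RNAi and from 0.86 to 2.13 for overexpression. The upper ends, 1.08 and 2.13, are those after the length trend was subtracted. Of 63 list medians, 34 lay outside the central 95% of random lists and 26 to 35 under other settings. Of the 63, 12 changed sign under at least 1 setting, 8 of them after length; 2 of these had lain outside the central 95%: the histone list turned to -0.25 in RNAi with no filter, and the mitochondrial ribosomal list to -0.015 in overexpression after length. Of 31 named RNAi calls, 23 passed after the length correction, 19 at q of 0.01, 11 with Benjamini-Hochberg recomputed over all genes and 7 when recentred with p from the statistic; of 38 for overexpression, 15, 16, 0 and 4 did (Cuffdiff's p, with all 38 at an unadjusted p of 0.05 or less). None of these folds changed sign.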

Other observations

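The tests of unspliced RNA, of the control libraries, of the glue and fat body genes and of the 3R segment were chosen only after the results were seen; the length correction was set out before its counts were known. Genes named in this part outside the rule were chosen after their values were seen. In the RNAi-labelled group the ecdysone-induced genes Eig71Eb and Eig71Eg and the Jonah gene Jon99Fi were listed at 0 in the control and at 3.74, 2.73 and 1.28 in the RNAi-labelled group. In the overexpression-labelled group the Jonah gene Jon25Bi was at 0.353 in the control and 11.1 and was not called. The dosage compensation RNA roX2 was at 319 in the control, 671 in the RNAi-labelled group and 906 in the overexpression-labelled group and was not called.

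Long transcripts were lower and short ones higher in both treated groups. A trend with transcript length was a candidate explanation of part of the falls: 24 of 69 lowered RNAi genes and 22 of 121 lowered overexpression genes passed after it was subtracted (15 of 60 and 18 of 117 with a fold and a length), against a fixed threshold, while the subtraction took 25.4% and 33.6% off their median fold (from -2.42 to -1.81, quartiles -2.19 and -1.42, and from -2.40 to -1.59, quartiles -1.90 and -1.29). Less unspliced RNA was not decided. Within bins of transcript length the rank correlation of fold with intronic length was 0.0513 for RNAi and 0.0358 for overexpression. No negative trend was therefore seen. No intronic reads were available, and unspliced RNA adds exonic reads too, so its loss need not give such a trend. The control libraries as the whole source were argued against, since length still went with the fold of overexpression over RNAi (rho = -0.296), but its medians at both ends of the length range lay 0.17 apart against 1.73 and 2.01 for the treated groups over the control, so a property of the control could give most of the trend. The shortest bin understates how far the treated groups differed at short lengths. At 701 to 1000 nt their medians over the control were 0.20 for RNAi and 0.39 for overexpression, and at 8001 to 12000 nt -1.12 and -1.31. The small RNA share of FPKM was 39.4% in the control against 47.5% and 47.0%. Small RNA loci make up much of the short end of the trend, so the share and the trend cannot be told apart. RNA integrity or fragment size, which the labels do not give, and a loss of unspliced RNA stay open. So does a real effect of Hsromega dosage on long transcripts, as the tables confound all of these with the groups.

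Glue and fat body genes were higher in the RNAi-labelled group, and the design does not tell dissection and treatment apart as sources. The stage is given only as late in the third instar. A difference in stage between the groups therefore cannot be told apart from these, nor for the eye development and ecdysone lists. Fat body genes were also higher in the overexpression-labelled group, where all 7 expressed markers lay above the control at a median of 1.40. More of the salivary gland RNA that the control also holds was argued against, since 1 source keeps its genes in 1 ratio and the log2 folds of the 5 Sgs genes with FPKM of 5 or more had an SD of 2.47, from 1.01 for Sgs3 to 6.66 for Sgs7. More of the fat body RNA that the control also holds could account for the fat body genes, whose 7 folds had an SD of 0.622; 6 of the 7 were at FPKM of 1 or more in the control, with Lsp2 highest at 36.2 in the RNAi-labelled group. Gland tissue of another stage and strain differences in the Sgs genes were not tested, and an effect of the treatment stays open.

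A segment of chromosome 3R, 12222387 to 12240527, had 10 neighbouring loci with 8 distinct spans, from CG10014 to CR44036, under 10% of the control in the RNAi-labelled group and 8 of them listed at 0. They stood at 0.103 to 2.35 in the control, and 1 of them was that low in the overexpression-labelled group. Scattered zeros of low loci were argued against: a run of 8 distinct low loci near 0 did not occur in 10000 permutations of the 72 near-zero loci among 3013 low loci, whose longest was 4 (permutation p = 0.0001, the smallest they can give). Loss of a DNA segment in the RNAi stock was not decided: 10 of the 10 loci were low (a count of 11 was written when the test was set out), but the segment had been picked by these low loci, and of its expressed neighbours CG4860 was at 23.3 in the control, 19.9 in RNAi and 18.5 in overexpression, and the locus of CG44037 and svp at 7.77, 2.71 and 2.02. No DNA was sequenced, and this loss and a regional effect of the treatment both stay open.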
